A study of Homo sapiens with 9 samples.

How the data were processed

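Total RNA of 9 LNCaP cultures was extracted with Trizol and hybridised as biotin-labelled cRNA to Affymetrix high-throughput human genome arrays, per the labels' protocols and the probe annotation. The deposited values are intensities on a linear scale, 1 per probe set and array, made by the authors with RMA, per the submitters' processing notes. RMA corrects background, brings the arrays to a common distribution and summarises the probes of a set; its version and probe definitions are not given in the sources used here. Such between-array normalization removes differences in total RNA and can shift genes where many move in one direction. The table was named linear from its values and log2 was taken with a pseudocount of 0, as had been provided for before the data were examined. No control probe sets were among the rows used, so that the ratio of 3' to 5' signal was not checked, and scan dates are not given in the sources used here, so that array batches were not tested. For arrays, the number per group limits the precision; the median standard error of a log2 fold change was 0.13.

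Of 22215 probe sets, 19724 have 1 gene in the annotation table, 568 have several and 1923 have none listed. Gene IDs of 19707 probe sets were found in the reference table of genes, from which their current symbols were taken. The 12165 genes were each represented by the probe set with the highest mean over the 9 arrays, and 4505 of them had more than 1 probe set. No gene that the text names had a probe set past the threshold in the other direction.

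Groups were taken from the labels: vehicle, androgen, and androgen plus celastrol, with 3 arrays each. All 9 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, eBayes without trend, 6 residual and 2.7 prior degrees of freedom), and the 3 comparisons between groups were drawn from this fit. P-values were adjusted by Benjamini and Hochberg over genes, and 0.05 was the threshold. A p-value measures the spread between these cultures. In 24 gene lists fixed before the data were examined, members were counted by their adjusted p over all genes and over the list alone. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 72 tests, and again with an estimated correlation and with fry. With the preset correlation 31 of the 72 tests were called, with an estimated correlation 18 and with fry 50. Unless another test is named, a list called or not called in the text refers to camera at the preset correlation. The list of genes named in the text followed a rule fixed before the data were examined: the 8 largest rises and falls per comparison (5 against vehicle for the combined treatment) among genes past the threshold whose arrays did not overlap, up to 4 members per list past the threshold and up to 2 that did not pass, the 6 most opposed and 4 not opposed genes per direction, and KLK3, KLK2, TMPRSS2, FKBP5, HSPA1A, HSPA1B, HSP90AA1 and HMOX1; fewer were printed where they repeat. Genes named because 5 or fewer members of a list moved in a direction (such as DNAJB1, DNAJA1, PEG3, DDC, PIK3R3, EPCAM and CDKN1A), values of a named gene in another comparison, and genes named for the part of their androgen response lost were chosen after their values were seen. Members of the lists and of that rule that are not among the 12165 genes were not analysed here.

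Opposition between androgen and celastrol was counted with Fisher's exact test against genes not called for androgen. Intervals of shares were computed with scipy 1.17.1 by the Wilson score method. The chance overlap from shared arrays was simulated 100 times, and each androgen array was held out in turn. The fit was tested on simulated data with 12165 genes, of which 50 changed at each of 4 sizes. For the androgen comparison it called 14%, 84%, 98% and 100% of genes with changes of 0.5, 1, 2 and 3 on the log2 scale and 3 of 11965 unchanged genes. For the celastrol comparison these were 28%, 86%, 98% and 100%, and 8 of 11965. The simulated noise was independent between genes and arrays, with equal spread on every array, and fewer genes changed than were called in the real data. These shares therefore do not give the sensitivity or error rate of the fit on the real data.

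The labels number the replicates 1 to 3 in each group. Correlations of deviations from the group means, over genes, between arrays of the same number were 0.40, 0.37 and 0.63 for vehicle and androgen, so that the numbers were taken as paired for that comparison. Vehicle array 2 correlated slightly more with androgen array 1 (0.41), so that the pairing of numbers 1 and 2 is uncertain. The counts, standard errors and p-values printed for androgen against vehicle come from the fit without a replicate term. With the replicate block, run as an alternative, 1406 genes were called for androgen, against 1583 without it. For androgen and androgen plus celastrol the correlations were -0.09, 0.21 and -0.19, and for vehicle and androgen plus celastrol -0.26, 0.11 and -0.29, so that there the numbers were taken as names. Alternatives were the replicate block, fits of the compared groups alone, a variance trend with robust estimation, array weights, omission of the dimmest 40% of genes, the mean of all probe sets or all probe sets counted, median subtraction, cyclic loess, a 2-fold minimum, and omission of each array in turn. Quantile normalization on top of the deposited values, the block within the compared groups and the omission of 3 arrays together were added after seeing the data. Figures were drawn with matplotlib 3.10.9.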

Results

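LNCaP is a human prostate cancer cell line whose growth and secretory gene programme depend on androgen. RNA was profiled on Affymetrix arrays in 9 cultures after 2 days in charcoal-stripped serum, which is depleted of steroid hormones. The cells then received vehicle (ethanol and DMSO), 1 nM of the synthetic androgen R1881, or 1 nM R1881 together with 1.25 µM celastrol, a triterpenoid from the thunder god vine. Each group held 3 arrays that the labels call biological replicates, with no further statement of how the cultures were separated. The labels give 24 h of treatment for the vehicle and the androgen plus celastrol arrays. For the 3 androgen arrays the descriptions, the treatment protocol and the series design give 24 h, while the titles give 6 h. The data do not settle this conflict, which applies to every comparison with these arrays. Median intensity lay between 72.2 and 80.2 on the 9 arrays. Vehicle array 3 stood apart: the standard deviation of its gene-wise deviations from the group mean was 0.31 on the log2 scale, against 0.20 for the next array, and its upper quartile was 332.5 against 377.4 to 408.7 on the others. Log2 fold changes below are given with the standard error of the limma fit (3 arrays per group), and adjusted p refers to the Benjamini-Hochberg adjustment over 12165 genes.

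The comparison of androgen with vehicle asked which genes the hormone moved in starved cells. Androgen raised the kallikrein KLK2 by 4.98 ± 0.26, from a mean intensity of 195 ± 72.9 to 5856 ± 423 (SD, n = 3), and KLK3, which encodes prostate-specific antigen, by 2.15 ± 0.08. FKBP5, a co-chaperone of steroid receptors, rose by 4.49 ± 0.14 and the membrane serine protease TMPRSS2 by 3.15 ± 0.15. Genes of cholesterol synthesis and uptake, polyamine metabolism, protein folding in the endoplasmic reticulum and secretion were also higher. The interleukin 1 receptor antagonist IL1RN changed by -3.50 ± 0.16, and UGT2B17, which conjugates androgens for removal, by -3.38 ± 0.10. In all, 1583 of 12165 genes changed, 872 upwards and 711 downwards, and 369 of them at least 2-fold. Among the largest rises were also the transcription factor SNAI2 (4.12 ± 0.20), GNMT (3.72 ± 0.19), EAF2 (3.69 ± 0.19), the peptide transporter SLC15A2 (3.55 ± 0.18) and HPGD (3.49 ± 0.11), which inactivates prostaglandins. Among the largest falls were butyrylcholinesterase BCHE (-3.39 ± 0.15), MID1 (-2.91 ± 0.08), the microtubule-binding MAPRE2 (-2.90 ± 0.15) and MYRIP (-2.79 ± 0.24). The adjusted p of each gene named in this paragraph lay below the 0.05 threshold, with 9.491e-05 for MYRIP and 4.839e-06 for KLK2, and the arrays of the 2 groups did not overlap.

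Of the 31 measured members of the fixed list of androgen-induced genes, 29 rose, none fell and 2 did not pass, with a median of 2.06 and the same 29 adjusted over the list alone (camera, adjusted p = 2.49e-43). STEAP1 (-0.04 ± 0.08) and TRPM8 (-0.08 ± 0.12) were the members that did not pass. Of 18 androgen-repressed genes, 13 fell, 1 rose and 4 did not pass, and 13 fell and 2 rose adjusted over the list alone (adjusted p = 3.34e-13), with 2 past the threshold upwards when each array's median was subtracted. Besides BCHE and UGT2B17, SERPINI1 changed by -2.97 ± 0.20 and the chemokine receptor ACKR3 by -2.79 ± 0.12, while AKAP12 rose by 1.30 ± 0.12. UGT2B17 and other UGT2B genes, like KLK2 and KLK3, are close relatives in sequence, so that the split between them is uncertain.

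Secretory genes moved with the hormone. Of 17 genes of N-glycosylation and the secretory pathway, 14 rose and none fell, and 15 rose adjusted over the list alone (median 0.68, adjusted p = 1.73e-15). SEC24D, a coat component of vesicles leaving the endoplasmic reticulum, rose by 1.97 ± 0.13, the signal peptidase subunit SPCS3 by 1.53 ± 0.18 and UAP1 by 1.21 ± 0.08. Of 19 genes of the unfolded protein response, 14 rose and none fell, also adjusted over the list alone (median 0.50, adjusted p = 9.80e-15). The chaperone partner DNAJB9 rose by 2.33 ± 0.16, SDF2L1 by 1.42 ± 0.17 and HERPUD1 by 1.07 ± 0.07.

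Metabolic lists rose as well. In cholesterol synthesis and uptake, 13 of 17 genes rose and TM7SF2 fell, and 14 rose and 1 fell adjusted over the list alone (median 0.69, adjusted p = 5.95e-12). HMGCS1, which makes the precursor of mevalonate, rose by 1.57 ± 0.14 and IDI1 by 1.01 ± 0.08. INSIG1, which rose by 1.15 ± 0.08, is known as a brake on sterol synthesis. In fatty acid synthesis, 6 of 11 genes rose and 1 fell, also adjusted over the list alone (adjusted p = 0.000408, and adjusted p = 0.142 with an estimated correlation). FASN rose by 1.01 ± 0.16 and FADS1 by 0.87 ± 0.09, while the elongase ELOVL6 changed by -0.68 ± 0.07. In polyamine synthesis, 4 of 8 genes rose and AZIN1 fell, and 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.000446). Spermine synthase SMS rose by 1.75 ± 0.13 and ornithine decarboxylase ODC1 by 1.34 ± 0.07. SAT1, which rose by 1.51 ± 0.08, is known to start the breakdown of polyamines. The fall of AZIN1 did not pass when the probe sets of a gene were averaged (adjusted p = 0.0545). Smaller shifts were called for mitosis genes (median 0.23, 2 of 29 genes past the threshold and 2 adjusted over the list alone, adjusted p = 8.33e-05) and for proteasome subunits (median 0.18, 3 of 28 past the threshold and 6 adjusted over the list alone, adjusted p = 0.000387). Neither was called with an estimated correlation, at adjusted p = 0.388 for mitosis and adjusted p = 0.397 for the proteasome. The number of mitosis genes past the threshold was 0 without androgen replicate 1, 1 without androgen replicate 2 and 4 without androgen plus celastrol replicate 3, and the proteasome median was 0.08 without vehicle replicate 3. With each array's median subtracted, 6 mitosis genes and 7 proteasome genes passed, and both lists were still called at the preset correlation in each of these settings.

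In the androgen comparison 28.3% of genes had arrays that did not overlap between the groups, where chance gives 10%. The split became 1182 upwards and 529 downwards with each array's median subtracted, 864 upwards and 972 downwards without vehicle replicate 3, 645 upwards and 433 downwards without androgen replicate 2, and 1417 upwards and 1837 downwards (3254 genes) with array weights that had not converged.

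Androgen plus celastrol was compared with androgen alone to show what celastrol changed while the hormone was present. Genes that respond to oxidants and to amino acid or translation stress were higher with celastrol than with androgen alone, and mitosis genes were lower. The unsettled treatment time of the androgen arrays may contribute to differences in this comparison. Heme oxygenase HMOX1 rose by 6.27 ± 0.26, from a mean intensity of 70.2 ± 16.0 to 5375 ± 989 (SD, n = 3). The stress transcription factor DDIT3 rose by 2.70 ± 0.14, and topoisomerase TOP2A, which untangles chromosomes in dividing cells, changed by -2.25 ± 0.14. In all, 1976 genes changed, 1095 upwards and 881 downwards, and 315 of them at least 2-fold. The largest rises included the aldo-keto reductases AKR1C2 (6.94 ± 0.17) and AKR1C1 (6.65 ± 0.19), near-identical in sequence and therefore uncertain as separate genes, NIBAN1 (4.02 ± 0.22), the small heat shock protein CRYAB (3.43 ± 0.12), GPNMB (3.26 ± 0.09), FGF13 (3.23 ± 0.14) and the carbonyl reductase CBR3 (2.85 ± 0.10). The largest falls included UGT2B28 (-2.71 ± 0.16), the ribonucleotide reductase subunit RRM2 (-2.49 ± 0.20), prostatic acid phosphatase ACP3 (-2.41 ± 0.10), SPOCK1 (-2.21 ± 0.23), SLC15A2 (-2.20 ± 0.18) and TM4SF1 (-2.18 ± 0.21). Each of these genes passed the threshold, with adjusted p = 4.38e-06 for HMOX1 and 0.000325 for SPOCK1, and the arrays of the 2 groups did not overlap.

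Of 23 oxidative stress genes, 21 rose and none fell, also adjusted over the list alone (median 1.07, adjusted p = 1.54e-20). Of 23 genes of the integrated stress response, 21 rose and none fell, and 21 rose and 1 fell adjusted over the list alone (median 1.14, adjusted p = 1.21e-18), with 1 falling over all genes without vehicle replicate 3 or with each array's median subtracted. The cystine transporter SLC7A11, which stands in both lists, rose by 1.94 ± 0.10, its partner SLC3A2 by 1.92 ± 0.17 and the glutathione-degrading CHAC1 by 1.97 ± 0.10. Among proteasome subunits, 18 of 28 rose and none fell, and 23 rose adjusted over the list alone (median 0.39, adjusted p = 1.23e-12, and adjusted p = 0.0880 with an estimated correlation). PSMD12 rose by 0.76 ± 0.08 and PSMB2 by 0.67 ± 0.07. Of 7 metallothioneins, which bind metal ions, 6 rose, also adjusted over the list alone (median 1.74, adjusted p = 1.13e-08, and adjusted p = 0.0880 with an estimated correlation). Probe sets of this family can bind several members, so that MT1G (1.95 ± 0.12) and MT1X (1.77 ± 0.13) are uncertain as separate genes. The unfolded protein response rose further over androgen alone in 6 of 19 genes, also adjusted over the list alone (median 0.23, adjusted p = 0.00145), with DNAJC3 at 0.92 ± 0.11. That count was 2 without androgen replicate 1 or androgen replicate 2 and 3 without androgen plus celastrol replicate 2, and the median was 0.12 without androgen replicate 3. Of 17 secretory genes 6 rose, and 10 rose and 1 fell adjusted over the list alone (median 0.35, adjusted p = 0.00471, and adjusted p = 0.0619 with an estimated correlation), and 3 rose without androgen replicate 2.

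The heat shock list was not called as a whole by camera (median 0.02, adjusted p = 0.779). The fry test, which does not compare a list with other genes, called it upwards (adjusted p = 0.000602). Of its 25 genes 4 rose and 3 fell, and 5 rose and 3 fell adjusted over the list alone. The risers CRYAB (3.43 ± 0.12), HSPB8 (2.23 ± 0.13), DNAJB4 (1.52 ± 0.09) and HSPA1L (0.64 ± 0.11) stood beside falls of DNAJB1 (-0.55 ± 0.08), HSPA8 (-0.48 ± 0.07) and DNAJA1 (-0.35 ± 0.09). The DNAJA1 call was lost without androgen replicate 1, 2 or 3 or androgen plus celastrol replicate 1 or 2 (adjusted p = 0.0554 to 0.120). It was also lost with the replicate block (0.0729), with the block within the compared groups (0.128) and when the probe sets of a gene were averaged (0.109). The major cytosolic chaperones HSP90AA1 (0.05 ± 0.07, adjusted p = 0.723) and HSPA1B (-0.14 ± 0.08, adjusted p = 0.327) did not pass, and HSPA1A was near the bottom of the intensity range. HSPA1A and HSPA1B are near-identical copies and uncertain as separate genes.

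Of 29 mitosis genes, 27 fell and none rose, and 29 fell adjusted over the list alone (median -1.05, adjusted p = 9.78e-26). Besides TOP2A, KIF20A changed by -1.71 ± 0.14, the spindle motor KIF11 by -1.44 ± 0.20 and the proliferation marker MKI67 by -1.41 ± 0.25. Of 30 DNA replication genes, 21 fell and none rose, and 22 fell adjusted over the list alone (median -0.77, adjusted p = 1.91e-15, and adjusted p = 0.0942 with an estimated correlation). Thymidylate synthase TYMS changed by -1.76 ± 0.18, CDC45 by -1.28 ± 0.10 and the helicase subunit MCM7 by -1.16 ± 0.12. Of 11 fatty acid synthesis genes 3 fell and 2 rose, and 8 fell and 2 rose adjusted over the list alone (median -0.29, adjusted p = 0.0325, and adjusted p = 0.386 with an estimated correlation). ACLY changed by -0.61 ± 0.10 while ELOVL6 rose by 1.40 ± 0.07. This list call was lost without androgen replicate 1 (adjusted p = 0.0511), androgen replicate 3 (0.0632) or androgen plus celastrol replicate 2 (0.0887). It was also lost without vehicle replicate 3, androgen replicate 3 and androgen plus celastrol replicate 1 together. The number of its genes that fell was 1 without androgen replicate 1 and 6 without vehicle replicate 3. The cholesterol list was not called (4 of 17 rose and 1 fell, 5 rose and 1 fell adjusted over the list alone, adjusted p = 0.773). Without any 1 androgen array, or without androgen plus celastrol replicate 1 or 3, 2 of its genes rose. The number that fell was 0 without androgen replicate 1 or 3, without androgen plus celastrol replicate 1 or 2, or without vehicle replicate 3, androgen replicate 3 and androgen plus celastrol replicate 1 together, and 2 without vehicle replicate 3 or with cyclic loess or quantile normalization. The polyamine list was not called either (3 of 8 fell and AZIN1 rose, also adjusted over the list alone, adjusted p = 0.316), with SMS at -1.22 ± 0.13.

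In the celastrol comparison 36.0% of genes had arrays that did not overlap, where chance gives 10%. Without androgen replicate 2 the count of changed genes was 1306 (711 upwards and 595 downwards) and without androgen replicate 1 it was 1353 (803 and 550), and no celastrol arm without androgen was analysed here, so that dependence of these changes on the hormone was not tested.

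**Figure D1:**
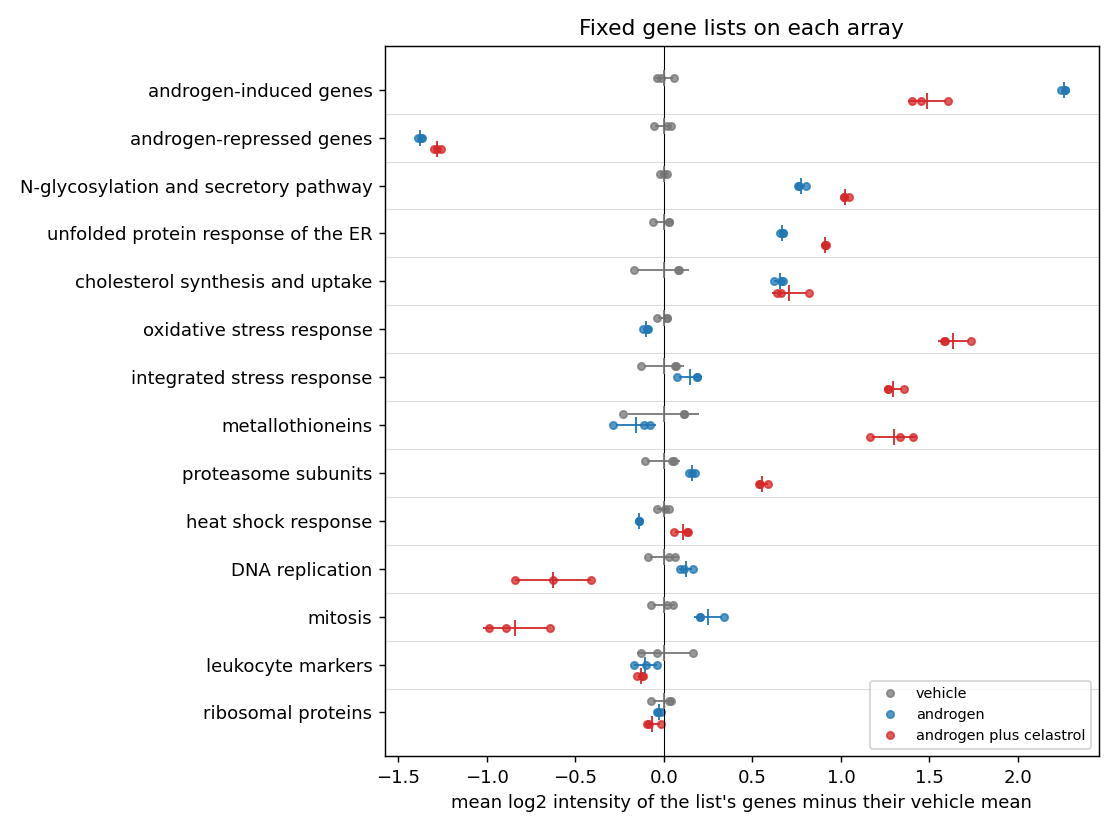
Mean log2 intensity of each fixed list's genes minus the vehicle mean of the same genes (x axis, log2), for 14 of the 24 lists (y axis). Points are arrays, 3 per group, vertical ticks are group means and horizontal bars are ±1 SD; the mitosis and DNA replication points of androgen plus celastrol lie left of every vehicle and androgen point, and the oxidative and integrated stress points lie right of them.

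Whether celastrol opposed the androgen response was asked gene by gene. Of the 872 genes that androgen raised, celastrol lowered 281, or 32.2% (95% Wilson interval 29.2 to 35.4), raised 127 further and left 464 without a call. Of the 711 genes that androgen lowered, celastrol raised 225, or 31.6% (28.3 to 35.2), lowered 73 further and left 413 without a call. Among the 10582 genes not called for androgen, celastrol lowered 4.98% and raised 7.02%. The odds ratios were 9.07 (Fisher's exact test, two-sided, p = 3.85e-123) and 6.13 (p = 8.40e-76). Celastrol raised 14.6% of androgen-raised genes further and lowered 10.3% of androgen-lowered genes further, against 7.02% and 4.98% of genes not called. Genes called for androgen were thus called more often in both directions, and the odds ratios may hold a part from that. The test also does not allow for the androgen arrays that both comparisons share with opposite sign. Genes are not independent of each other either. These p-values and intervals therefore describe the overlap and not its cause or its repeatability between cultures.

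Of the 31 androgen-induced list genes, 22 were lower with celastrol and none was higher, and 23 were lower adjusted over the list alone (median -0.73, camera, adjusted p = 2.16e-16). KLK2 changed by -1.51 ± 0.26, FKBP5 by -1.37 ± 0.14, KLK3 by -0.85 ± 0.08 and HPGD by -1.66 ± 0.11. TMPRSS2 stayed at -0.16 ± 0.15 (adjusted p = 0.574) and PMEPA1 at -0.07 ± 0.10 (adjusted p = 0.737), neither past the threshold. The androgen-repressed list was not called (adjusted p = 0.506). Of its 18 genes 3 rose and 5 fell, and 4 rose and 5 fell adjusted over the list alone, with a median of 0.03 and a mean of 0.10 although the test pointed downwards. SERPINI1 rose by 2.48 ± 0.20, ACKR3 by 1.48 ± 0.12 and BCHE by 1.10 ± 0.15. AKAP12 fell by 1.06, PEG3 by 0.61, DDC by 0.56, ADAMTS1 by 0.56 and PIK3R3 by 0.50 on the log2 scale, with the DDC call lost when the probe sets of a gene were averaged (adjusted p = 0.320). UGT2B17 (0.08 ± 0.10) and IL1RN (0.20 ± 0.16) did not pass. FGF13, at -2.28 ± 0.14 with androgen, and GPNMB, at -0.88 ± 0.09, were among the androgen-lowered genes that celastrol raised most.

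Both comparisons use the same androgen arrays with opposite sign, so chance alone favours opposite signs. In 100 simulations that kept the androgen effect and gave celastrol none, the share of androgen-raised genes with a celastrol change of opposite sign averaged 59.2% (highest 63.2%) against 64.3% observed, and for androgen-lowered genes 63.2% (highest 66.1%) against 67.8% observed. The simulated noise was independent between genes and arrays, while real deviations were correlated over genes (0.63 for vehicle 3 and androgen 3). The simulated ranges therefore do not bound what such noise can give, and these shares do not show an excess. The simulated share called in the opposite direction averaged 0% and 0.00165%, which follows from the near absence of celastrol calls in such simulations and does not measure what the shared arrays add to the observed shares. Independent lists of the same sizes would overlap in 63.2 and 64.0 genes. The covariance of the log2 fold changes was -0.042, against -0.013 simulated. With androgen calls made on 2 androgen arrays and celastrol measured against the one held out, which is assumed to vary like the arrays of the other groups, 11.5%, 9.15% and 9.91% of androgen-raised genes were called lower, against 1.01%, 0.749% and 0.829% of genes not called for androgen. For androgen-lowered genes 10.2%, 15.0% and 13.3% were called higher, against 1.13%, 1.39% and 1.58%. The array held out was not used for the androgen calls. Over androgen-raised genes the median celastrol change against it was -0.25, -0.16 and -0.16, against 0.01, 0.04 and 0.04 for genes not called. Over androgen-lowered genes it was 0.13, 0.21 and 0.18. These medians argue against noise of single androgen arrays as the whole cause. A deviation common to the 3 androgen arrays would remain, and the shares of the full data may hold a part from the shared arrays.

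**Figure D2:**
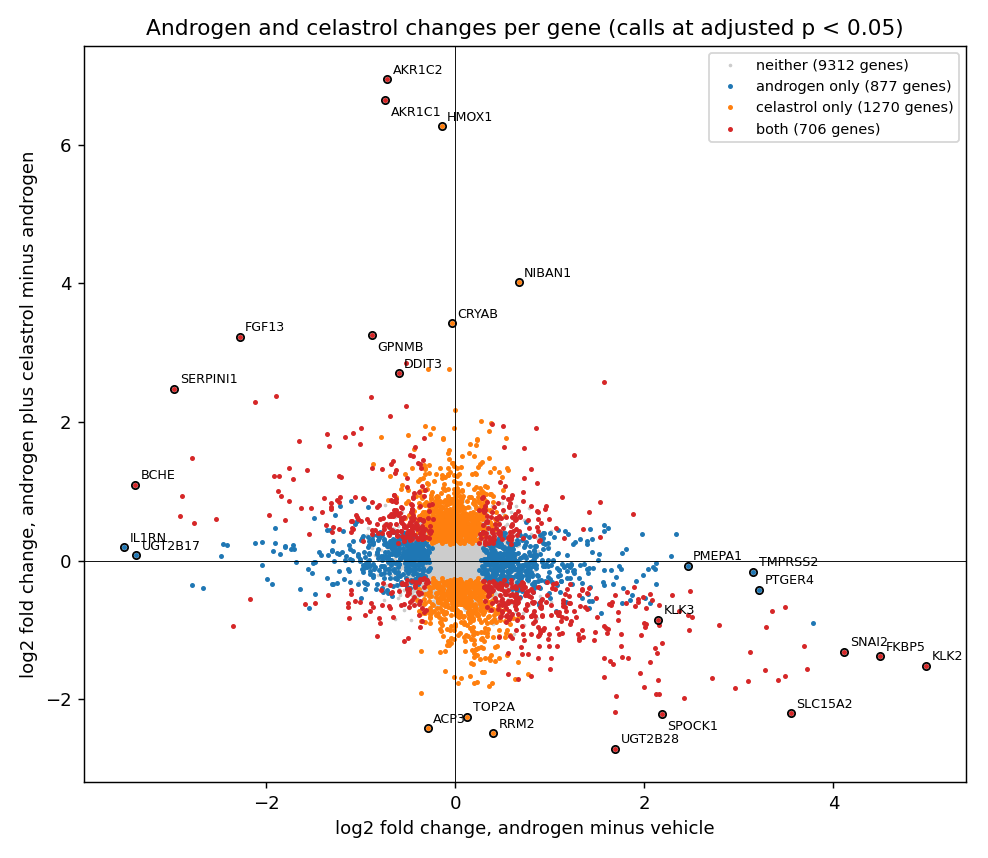
Log2 fold change of androgen minus vehicle (x axis) against androgen plus celastrol minus androgen (y axis) for 12165 genes, coloured by which of the 2 comparisons passed an adjusted p of 0.05. KLK2, FKBP5 and SLC15A2 lie at lower right and SERPINI1 and FGF13 at upper left, TMPRSS2 lies near the horizontal axis, and HMOX1, AKR1C1 and AKR1C2 lie at the top.

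Androgen plus celastrol was compared with vehicle to show how far the treated cells still lay from starved cells. KLK2 remained 3.47 ± 0.26 above vehicle, FKBP5 3.12 ± 0.14, TMPRSS2 2.99 ± 0.15 and KLK3 1.30 ± 0.08. The largest rises were AKR1C2 (6.22 ± 0.17), HMOX1 (6.13 ± 0.26), AKR1C1 (5.90 ± 0.19), NIBAN1 (4.69 ± 0.22) and the noncoding host transcript MIR22HG (4.15 ± 0.30). The largest falls were IL1RN (-3.31 ± 0.16), COLEC12 (-3.30 ± 0.11), UGT2B17 (-3.30 ± 0.10), MYRIP (-3.14 ± 0.24) and UGT2B15 (-3.06 ± 0.17). In all, 2840 genes changed, 1622 upwards and 1218 downwards, and 580 of them at least 2-fold, with arrays that did not overlap for 37.2% of genes where chance gives 10%. Of the 872 androgen-raised genes, 609 (69.8%) were still called higher than vehicle with celastrol present, against 116.3 for independent lists of these sizes. Simulations that kept the androgen effect and set the combined treatment at vehicle gave a mean of 0.01 such genes, which follows from the near absence of calls against vehicle and does not measure what the shared arrays add. Of the 711 androgen-lowered genes, 435 (61.2%) were still called lower, against 71.2 for independent lists. Among the 281 androgen-raised genes that celastrol lowered, 100 were still called higher than vehicle, and among the 225 that it raised, 51 were still called lower. The vehicle arrays stand in both comparisons and part of this overlap may come from them.

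Of the androgen-induced list 25 of 31 genes were above vehicle and none below, and 27 adjusted over the list alone (median 1.57, adjusted p = 4.18e-19). Of the androgen-repressed list 13 of 18 were below and none above, and 14 adjusted over the list alone (adjusted p = 1.26e-11), with 1 above without vehicle replicate 3, alone or together with androgen replicate 3 and androgen plus celastrol replicate 1. The unfolded protein response was above vehicle in 18 of 19 genes, and in 19 adjusted over the list alone (median 0.69, adjusted p = 5.26e-14), and the secretory list in 14 of 17, also adjusted over the list alone (median 0.98, adjusted p = 9.00e-13). Integrated stress genes were above vehicle in 22 of 23, also adjusted over the list alone (adjusted p = 1.80e-17), and oxidative stress genes in 20 of 23, or 21 adjusted over the list alone (adjusted p = 1.59e-15). Proteasome subunits were above vehicle in 25 of 28, also adjusted over the list alone (median 0.48, adjusted p = 2.98e-14, and adjusted p = 0.0811 with an estimated correlation). Metallothioneins were above in 6 of 7, also adjusted over the list alone (adjusted p = 1.66e-06, and adjusted p = 0.138 with an estimated correlation). Cholesterol genes were above in 12 of 17, also adjusted over the list alone (adjusted p = 2.34e-08, and adjusted p = 0.0880 with an estimated correlation), and polyamine genes in 4 of 8, or 6 adjusted over the list alone (adjusted p = 0.00145), with 2 of 8 without vehicle replicate 1. Mitosis genes lay below vehicle in 22 of 29, or 27 adjusted over the list alone (median -0.83, adjusted p = 1.95e-14, and adjusted p = 0.0880 with an estimated correlation). DNA replication genes lay below in 19 of 30, or 20 adjusted over the list alone (median -0.50, adjusted p = 3.04e-09, and adjusted p = 0.216 with an estimated correlation). TOP2A changed by -2.12 ± 0.14 and RRM2 by -2.09 ± 0.20 against vehicle. The fatty acid list (3 of 11 above and 1 below, also adjusted over the list alone, adjusted p = 0.177) and the heat shock list (4 of 25 above and 4 below, 4 above and 6 below adjusted over the list alone, adjusted p = 0.558) were not called. The number of fatty acid genes below was 0 in the replicate block, without vehicle replicate 3, androgen replicate 3 and androgen plus celastrol replicate 1 together, and without any 1 array except vehicle replicate 3 or androgen plus celastrol replicate 3, and the number of heat shock genes below was 8 with cyclic loess or quantile normalization.

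**Figure D3:**
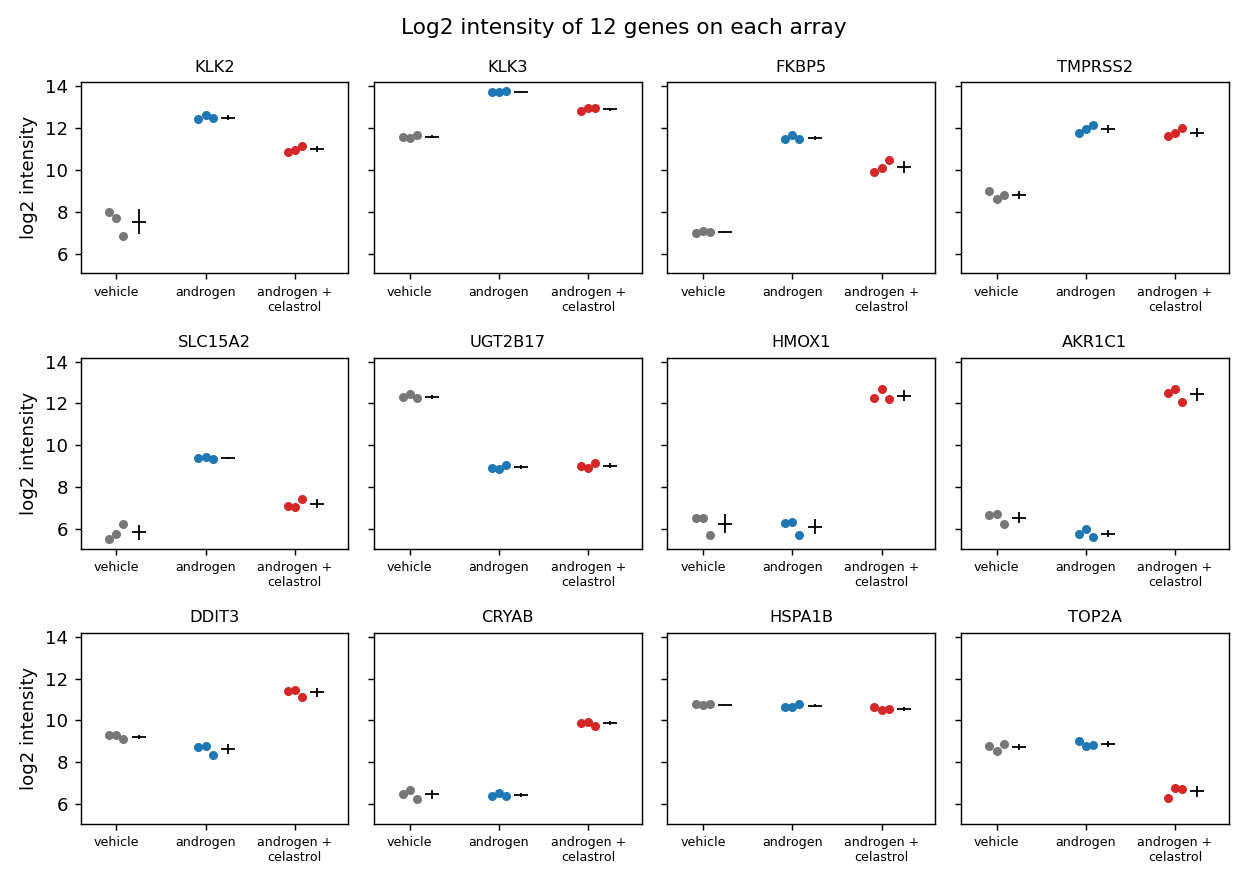
Log2 intensity (y axis) of 12 genes on the 3 arrays of each group (coloured points), with the group mean and ±1 SD beside them in black. HMOX1, AKR1C1, DDIT3 and CRYAB lie highest with celastrol, TOP2A lies lowest there, KLK2, KLK3, FKBP5 and SLC15A2 lie between vehicle and androgen, and TMPRSS2 and UGT2B17 lie at the androgen level.

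Over the 3 groups together, 3182 of 12165 genes differed in limma's moderated F test at an adjusted p of 0.05.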

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

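The tests of a smooth brightness trend on vehicle array 3, its bootstrap interval, both tests of the mitosis genes and the splits within replicate numbers were chosen only after the result was seen. Probe sets outside the gene counts also changed at an adjusted p of 0.05. Among 1923 probe sets with no gene listed, 139 changed with androgen, 148 with celastrol over androgen and 247 with the combined treatment over vehicle. Among 568 probe sets of several genes, the counts were 49, 51 and 83. These were singled out as signals in data that the comparisons do not use.

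Vehicle array 3 stood apart from vehicle arrays 1 and 2, with a spread of deviations 1.53 times that of the next array. A distortion of the signal with brightness on that array would bring this ratio under 1.5 after quantile normalization, a bound set before that ratio was computed. The ratio was then 1.525, above that bound, but its 95% bootstrap interval over genes (1.489 to 1.543, 200 draws) includes the bound. The bound also lay close to the ratio as deposited (1.528), so that passing it decides nothing. Quantile normalization left the ratio almost unchanged, which argues against a distortion that it removes as the whole cause. A smooth trend with brightness held 17.5% of the variance of the deviations, which argues against such a trend as the whole cause, and removing it left a ratio of 1.45. The androgen-induced list argues against admixture of androgen-treated cells or a swap with an androgen array. Its median on this array was 0.00358 log2 from the other vehicle arrays, against 0.21 for 10% of the androgen effect. Deviations of vehicle array 3 correlated at 0.63 with those of androgen array 3, so that they were not wholly particular to it. A cause shared by these 2 arrays was not tested. No biological explanation was tested, since the design names none.

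Androgen-induced genes were lower with celastrol. Noise of the shared androgen arrays was predicted to shrink the effect measured on the array held out. The smallest ratio of the held-out to the full median was 1.05. The held-out medians came from 615, 645 and 696 genes called on 2 androgen arrays, and the full median from 872. A ratio between different gene sets does not measure the part that shared noise gives. The array held out had no part in the calls, and its medians of -0.25, -0.16 and -0.16 argue against noise of single androgen arrays as the whole cause. A general lowering of genes of that brightness is argued against by random lists, since 0 of 10000 lists matched on mean level (0%) had a median as low as -0.15, and the lowest was -0.03. The called genes were selected on the shared androgen arrays and the random lists were not. The difference between them may therefore hold a part from that selection, and the share is no p-value for an effect of celastrol. A shorter treatment of the androgen arrays stays open and cannot be told apart from the groups. Their titles give 6 h, against 24 h in their descriptions, the treatment protocol and the series design. An effect of celastrol on the androgen response may be the biological explanation. It is likewise open while that conflict is unsettled, and the size of the part given by shared-array noise was not measured.

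Mitosis genes were lower with celastrol than with androgen alone. If celastrol had removed only a rise that androgen had brought, the combined treatment would lie near vehicle, but the list's median against vehicle was -0.83 (-0.8286) and each of the 3 celastrol arrays scored below each vehicle array, which argues against that as the whole cause. A shorter treatment of the androgen arrays cannot be told apart from the groups by the same value: the bound first set for it assumed that 24 h of androgen alone would leave these genes near vehicle, while a late fall with androgen would also give -0.83, and no other androgen group was analysed here. A lower number of dividing cells under celastrol is a candidate explanation that the design names through its treatment, as a hypothesis from the same data, and list calls for this pattern against vehicle were lost with an estimated correlation.

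Other splits of the arrays were fitted for each count. For androgen against vehicle, 1 of the 10 splits of 6 arrays, the real one, gave 1583 genes and the highest other gave 0. The other splits that part every pair of like-numbered arrays are among these and differ from the real one by calling 0 genes. For celastrol over androgen the real split, 1 of 10, gave 1976 and the highest other 0, and for the combined treatment over vehicle the real split, 1 of 10, gave 2840 and the highest other 0. With 10 splits the share can never fall under 0.05. Over the 3 groups, 1 of 100 drawn splits, the real one, gave as many as 3182 genes and the highest other gave 1121, from draws that ignore the replicate numbers. Among the 36 splits that put 1 array of each number in every group, 1, the real one, gave 3182 and the highest other 818. Both shares lie under 0.05 and are the smallest that these sets allow, which argues against a chance arrangement of arrays. The set of 36 was chosen after the result was seen. Splits do not address a batch that follows the groups, which was not tested.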

How the results depend on the processing

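Quantile normalization, the block within the compared groups and the omission of 3 arrays were chosen after seeing the data. Of 5267 alternative values for 312 results of 207 named genes, 4936 kept their direction and side of the threshold, 141 newly passed, 190 no longer passed and 0 reversed. Array weights, which did not converge, gave 3254 genes for androgen and 4934 in the F test. A 2-fold minimum left 369, 315 and 580 genes for androgen, celastrol over androgen and the combined treatment over vehicle, fewer by construction, and gave shares opposed of 21.3% and 15.1%. The share of androgen-raised genes that celastrol lowered was 35.7% with cyclic loess, 37.6% with quantile normalization and 36.3% without vehicle 3, androgen 3 and celastrol 1. The share of androgen-lowered genes that it raised was 35.9% without the dimmest genes and 27.3% with quantile normalization. With an androgen array held out, which leaves 1 array in an arm that is assumed to vary like the other groups, these shares were 11.5%, 9.15% and 9.91%, and 10.2%, 15.0% and 13.3%. The causes of the moved shares were not tested. Leaving out 1 array gave 1306 to 1601 genes for celastrol over androgen (lowest without androgen 2), 25.4% to 40.2% for the raised share (highest without vehicle 3) and 25.7% to 33.6% for the lowered share. Without the 3 arrays, 2020, 2396 and 3166 genes were called. Of the 72 list tests, 18 were called with an estimated correlation and 50 with fry, which does not compare a list with other genes. No list call turned its median's sign under any scaling, the block or an array left out.

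With the replicate block, 1406 genes were called for androgen, 1716 for celastrol over androgen and 2688 for the combined treatment over vehicle, and within the compared groups 1502 for androgen. The block ended the androgen calls of MT2A (adjusted p = 0.0552) and MX1 (adjusted p = 0.0778) and, within the compared groups, of ATF3 (0.0589) and CLDN7 (0.0550); it changed no other androgen call of a named gene and no list call. For celastrol over androgen the arrays share only a number, not every array correlated best with its own, and the block within the groups gave 1516 genes. Genes near the bottom of the intensity range are the least certain.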

Other observations

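The test of a common fraction was chosen only after the result was seen. Several gene groups were not called as lists in any of the 3 comparisons at the preset correlation. Among luminal markers, the keratins KRT19 (1.95 ± 0.17) and KRT8 (1.64 ± 0.10) rose with androgen and KRT19 changed by -1.62 ± 0.17 with celastrol, while the list as a whole was not called (adjusted p = 0.316 and 0.662, and 0.419 for the combined treatment over vehicle). Of 12 luminal genes, 4 rose and EPCAM fell with androgen, and 4 rose and 3 fell adjusted over the list alone. The EPCAM call was lost without androgen replicate 1 (adjusted p = 0.0528) and with each array's median subtracted (0.0727), while 2 luminal genes fell without vehicle replicate 3, and 3 with cyclic loess or quantile normalization or without vehicle replicate 3, androgen replicate 3 and androgen plus celastrol replicate 1 together. Among p53 targets, GDF15, a secreted stress protein, rose by 2.76 ± 0.16 with celastrol and GADD45A by 0.79 ± 0.13, while SESN1 changed by -0.72 ± 0.08. CDKN1A and CCNG1 passed too, but lost their calls without androgen replicate 1, 2 or 3 or androgen plus celastrol replicate 2, CDKN1A also without replicate 3 and CCNG1 without replicate 1 of that group (adjusted p = 0.0507 to 0.0840 and 0.103 to 0.118). In all 4 of 15 rose and 2 fell, 5 and 2 adjusted over the list alone (adjusted p = 0.378), with 6 rising without vehicle replicate 3 and 7 without vehicle replicate 3, androgen replicate 3 and androgen plus celastrol replicate 1 together. For androgen the p53 list was not called (adjusted p = 0.122), but was called downwards with cyclic loess (adjusted p = 0.0430), without vehicle replicate 3 (adjusted p = 0.0168) and without vehicle 3, androgen 3 and celastrol 1 together, chosen after seeing the data (adjusted p = 0.0171), within a range of 0.0168 to 0.271 over the scalings, the block and the arrays left out. For the combined treatment over vehicle it had adjusted p = 0.736. Of 17 NF-kappaB targets, NFKBIA rose by 1.12 ± 0.14 and NFKB1 changed by -1.28 ± 0.14 with androgen (list adjusted p = 0.961 and 0.288, and 0.537 for the combined treatment over vehicle).

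In glycolysis, HK2 rose by 1.25 ± 0.15 and PFKM changed by -0.77 ± 0.08 with androgen, and ALDOA rose by 0.57 ± 0.08 with celastrol (list adjusted p = 0.272 and 0.513, and 0.152 for the combined treatment over vehicle). Among interferon-stimulated genes, BST2 rose by 0.90 ± 0.14, IFI44 by 0.88 ± 0.14 and IRF7 by 0.64 ± 0.12 with celastrol (list adjusted p = 0.319, and 0.199 for androgen and 0.954 for the combined treatment over vehicle). Fibronectin FN1, of the stromal list, changed by -1.31 ± 0.09 with androgen and rose by 0.83 ± 0.09 with celastrol (list adjusted p = 0.137 and 0.961, and 0.122 for the combined treatment over vehicle). The remaining marker lists were not called for androgen, celastrol over androgen or the combined treatment over vehicle: neuroendocrine (adjusted p = 0.354, 0.180 and 0.779), basal (0.729, 0.695 and 0.601), leukocyte (0.558, 0.773 and 0.506) and ribosomal proteins (0.695, 0.316 and 0.231). With androgen the heat shock (adjusted p = 0.223), integrated stress (0.105), oxidative stress (0.601), DNA replication (0.122) and metallothionein (0.288) lists were not called, and HSPA4L changed by -1.30 ± 0.17 there.

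A hypothesis that 1 common fraction of the androgen effect was lost in every androgen-induced gene was tested on the 29 list genes that androgen raised. The fraction lost is the celastrol log2 fold change with its sign turned, divided by the androgen log2 fold change. It is a share of the log2 change and not of the intensity. The median fraction lost was 33.2%, and 14 of the 29 departed from it at an adjusted p over the list below 0.05, 7 losing more and 7 less. This argues against a common fraction on the log2 scale. A common loss of intensity would give unequal log2 fractions, and it was not tested. KLK2 (30.4%), FKBP5 (30.5%) and KLK3 (39.4%) lay near the median and did not depart. C1orf116 lost 106.9% and SPDEF 76.6%, while TMPRSS2 lost 5.09% and PMEPA1 2.92%. A gene-dependent effect of celastrol may account for this, as may the unsettled treatment time of the androgen arrays, and the data do not separate them.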
